A study of Mus musculus with 23 samples.

How the data were processed

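The series holds RNA-seq libraries of mouse mammary cells, each made from approximately 2000 cells sorted by flow cytometry. Per the labels' protocols, full-length cDNA was made from polyA RNA with SmartSeq2 and amplified with 18 PCR cycles. It was then tagmented with the Nextera XT kit, amplified with 10 further cycles and sequenced from a single end with reads of 50 or 75 bp on an Illumina HiSeq instrument. The labels do not say which libraries had which read length. SmartSeq2 and Nextera XT do not mark strand and carry no molecular identifiers. Overlapping genes on opposite strands therefore cannot be told apart, and PCR copies are counted as reads.

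The 23 libraries form 9 groups, taken from the sample titles. Normal tissue gave 4 populations of 2 libraries each. They are fetal mammary stem cells (fMaSC) from embryonic day 18 and, from adult glands, basal cells, luminal progenitors and mature luminal cells. Tumours grown from transplanted PY230 cells, a mouse mammary tumour line, gave luminal SOX10 high, luminal SOX10 low and basal SOX10 high cells with 2 libraries each. Spontaneous tumours of C3-1-TAg mice, which express the SV40 T antigen in mammary epithelium, gave 5 SOX10 high and 4 SOX10 low libraries, all titled basal and called C3-1-TAg SOX10 high and low below. The normal and PY230 cells were of the C57BL6J strain and the C3-1-TAg cells of the FVB strain. The series' design text calls the libraries of a group biological replicates, and the labels do not tie a library to an animal or tumour. The sort markers and gates are not given in the sources used here.

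The deposited values are RPKM per gene, reads scaled to gene length and library size. They come in 3 tables that the authors made separately, 1 each for normal, PY230 and C3-1-TAg cells. Per the submitters' processing notes, the genome build was mm9 and the tools FastQC, HISAT2 2.0.5 and StringTie 1.3.1c. The gene annotation, the read totals and any filter are not given in the sources used here. The tables list 24391, 24511 and 24322 genes by symbol. In the C3-1-TAg table each value above 0 starts just over 2, while values between 0 and 2 fill the other tables. A constant of 2 was therefore taken off each value above 0 of that table, and the values as deposited were run as an alternative. Symbols of the C3-1-TAg table differ in their capitals from the others, and 2200 were respelled to match.

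RPKM holds no read counts, so the absolute depth of a library is unknown and no counting interval is given. The spacing of the low values gave the depth of a library relative to the first of its table, which ran from 0.75 to 1.35 in the PY230 table and from 0.64 to 1.27 in the C3-1-TAg table. In the normal table the spacing was too fine to read. Between 10056 and 12504 genes reached 1 RPKM in a library. Precision was judged from the spread between libraries: the median residual SD on the log2 scale was 0.27 in the normal, 0.17 in the PY230 and 0.39 in the C3-1-TAg table.

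Groups were compared only within a table, on log2(RPKM + 1), with limma 3.58.1 in R 4.3.3. A fold change on this scale understates the change of genes near 0. The model fitted all groups of a table together, without a term for the replicate number, with an intensity trend in the variance moderation. Genes entered with at least 1 RPKM in at least 2 libraries, or 4 for the C3-1-TAg table. The threshold was a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of single genes below are limma's, and all such tests were two-sided. Sox10 in C3-1-TAg cells was also tested with an exact permutation test.

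Gene lists fixed from textbook knowledge were tested with camera (preset correlation 0.01, then an estimated correlation) and fry, with adjustment over the lists of a comparison. Of the 24 lists, 8 cover basal and myoepithelial, luminal progenitor, hormone-sensing mature luminal, luminal and epithelial identity, mesenchymal transition, neural crest, fetal growth and imprinted, and cell cycle genes. A further 9 cover cartilage-type matrix, basement membrane, milk protein, antigen presentation and interferon, immediate early and heat shock, hypoxia and glycolysis, Notch signalling, Wnt target and ribosomal protein genes. The others hold markers of immune, endothelial, fibroblast, fat, red, skin keratinocyte, and Schwann or melanocyte cells. Lists with fewer than 3 measured members were counted but not tested. Csn3 and Lalba stand in both the luminal progenitor and the milk protein list, and Snai2 in the basal and mesenchymal lists. Hey1 stands in the luminal progenitor and Notch lists, and Jag2 in the basal and Notch lists. No list was chosen on these samples.

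Genes specific to a normal population, with an adjusted p under 0.05 and a log2 fold change of at least 1 against each of the other 3 populations, were tested as sets in the tumour comparisons. The SOX10 comparisons of the 2 tumour models share no library, so their fold changes were correlated across genes and their difference was tested in 1 limma model. That difference sets PY230 fractions titled luminal against C3-1-TAg fractions titled basal, of different strains. Genes named in the text were Sox10, per comparison up to 10 with the largest rise and 10 with the largest fall, and per list up to 4 with the largest change past the threshold. Where no member passed, the member with the highest mean was taken. The 10 had to pass the threshold, have libraries that do not overlap between the groups and a mean of at least 10 RPKM in the higher group, and carry no provisional, microRNA or small nucleolar RNA symbol. Genes in the marker plot were picked from the lists outside this rule, as were genes that the text says were picked or named after their values were seen. The lists, tests, naming rule and most alternatives were chosen before the data were examined.

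The alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, median-of-ratios size factors, the replicate number as a block, a fit on the 2 groups alone, and leaving out each library. Those added after the data were seen were the C3-1-TAg values as deposited, leaving out 2 C3-1-TAg libraries together, a crossed pairing of PY230 libraries, a block of the pairs of C3-1-TAg libraries seen in the values, the neural crest list without Sox10, an estimated correlation in the list tests, and the settings tried on the lists and on the difference between models. Gene order came from a GRCm38 annotation and was used only for which genes are neighbours, since the values were made on mm9. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

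The tests were checked on simulated data with 200 changed genes, drawn with the means and spread of each table. Genes and libraries were drawn independently, without the pairs seen among the C3-1-TAg libraries. Camera with an estimated correlation was not run on them. Its power is thus unknown, and a call lost with it does not argue against a list. Most real comparisons called far more genes, which eases the adjusted threshold. The shares below therefore hold for the simulated setting and need not carry over to the real comparisons. At a true log2 change of 1 the share recovered was 14.0% for fMaSC against basal cells, 10.0% against luminal progenitors and 11.0% against mature luminal cells. It was 7.0% for basal cells and 8.0% for mature luminal cells against luminal progenitors. For PY230 cells it was 59.0% for luminal SOX10 high against low and 57.0% for basal against luminal, and for C3-1-TAg cells it was 33.0%. At a log2 change of 2 the shares were 68.0%, 68.0%, 65.0%, 58.0%, 67.0%, 96.0%, 82.0% and 81.0% in the same order. False calls made up between 2.6% and 9.7% of the calls. For the difference between the tumour models 63.0% of true differences of 2 were recovered, with 6 false calls.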

Results

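Gene expression was measured by RNA-seq in 23 libraries of sorted mouse mammary cells. The normal gland was sampled as fetal mammary stem cells (fMaSC) of embryonic day 18 and as adult basal cells, luminal progenitors and mature luminal cells, with 2 libraries each. The tumour cells came from transplanted PY230 tumours (luminal SOX10 high, luminal SOX10 low and basal SOX10 high, 2 libraries each) and from spontaneous C3-1-TAg tumours (5 SOX10 high and 4 SOX10 low libraries, all titled basal). Values are RPKM ± SD, and a single number in parentheses after a gene is its log2 fold change. The 3 sets of samples were made as separate tables, so levels are compared only within a set. Between 10056 and 11349 genes reached 1 RPKM in the normal libraries, between 11918 and 12405 in the PY230 and between 11023 and 12504 in the C3-1-TAg libraries. In all 6 adult normal libraries the gene with the largest share of the RPKM was the nuclear RNA Malat1, at 6.3% and 11.5% in mature luminal cells, 3.5% and 3.9% in luminal progenitors and 3.5% and 5.9% in basal cells. In fMaSC it was the ribosomal protein gene Rplp0, at 1.4% and 1.3%. The libraries of a group are biological replicates, and with 2 per group a p-value rests on a spread estimated across the groups of a table.

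Sox10, a transcription factor of neural crest and embryonic mammary cells, gives the tumour fractions their names. It was 25.2 ± 1.4 RPKM in fMaSC, 6.36 ± 2.8 in adult basal cells, 8.24 ± 4.8 in luminal progenitors and 0.202 ± 0.17 in mature luminal cells (n = 2 each). It was higher in fMaSC than in each adult population (limma, adjusted p = 0.00634, 0.0151 and 1.3e-04). Basal cells and luminal progenitors did not differ in Sox10 beyond the spread (log2 fold change -0.28, adjusted p = 0.638), and mature luminal cells lay below luminal progenitors (-2.85, adjusted p = 0.00427). In PY230 tumours Sox10 was 84.0 ± 24 RPKM in the luminal SOX10 high, 12.3 ± 1.8 in the luminal SOX10 low and 75.1 ± 4.4 in the basal SOX10 high fraction. In C3-1-TAg tumours the 5 SOX10 high libraries averaged 143 ± 30 RPKM, the lowest at 91.9, and the 4 SOX10 low libraries 21.8 ± 18, the highest at 40.9. That difference of 3.19 on the log2 scale had p = 0.00794 in an exact two-sided permutation test over 126 splits, the smallest p this design allows. Over all genes limma's adjusted p was 0.454. The tumour fractions are named by SOX10, so these differences follow from how the fractions were set apart.

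**Figure D1:**
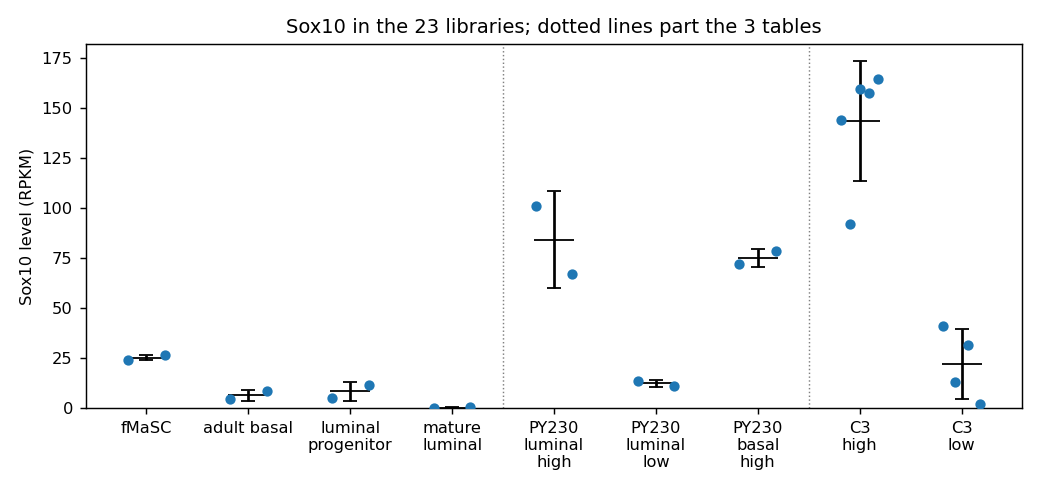
Sox10 level (RPKM) in each of the 23 libraries by group; points are libraries, horizontal lines the group means and bars 1 SD. Dotted lines part the 3 tables, between which levels are not compared, and the C3-1-TAg SOX10 high libraries all lie above the highest SOX10 low library at 40.9.

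The comparison of fMaSC with adult basal cells asked how the fetal cells differ from the adult population of the basal lineage. Genes of mitosis lay far higher in fMaSC. Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, was at 214 ± 7.6 RPKM against 0.457 ± 0.38 in basal cells (n = 2 each), and the mitotic kinase Cdk1 at 106 ± 0.45 RPKM against 0.294 ± 0.28. All 22 cell cycle genes were higher (22 adjusted over the list alone; camera, adjusted p = 1.2e-10, and adjusted p = 0.0357 with an estimated correlation). Imprinted and fetal growth genes were higher for 11 of 13 measured (11 higher and 1 lower adjusted over the list alone), among them H19 at 125 ± 5.7 RPKM against 0.382 ± 0.43 and Mest at 157 ± 0.88 RPKM against 1.85 ± 1.2. Lect1, a cartilage glycoprotein, had the largest rise at 365 ± 2.8 RPKM against 0.197 ± 0.28. All 5 measured cartilage-type matrix genes were higher (5 adjusted over the list alone), with Col9a1 at 33.9 ± 1.5 RPKM against 1.49 ± 0.31.

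Hormone receptor genes went the other way, and genes of basal and contractile cells went both ways. Of 16 basal and myoepithelial genes 9 were lower and 3 higher in fMaSC (9 and 4 adjusted over the list alone). Lower were smooth muscle myosin Myh11 at 0.659 ± 0.040 RPKM against 56.0 ± 21 and Krt17 at 39.5 ± 3.9 RPKM against 649 ± 317. Among the higher was smooth muscle actin (Acta2), picked here after its values were seen, at 621 and 608 RPKM in fMaSC against 306 and 135 RPKM. Of 13 hormone-sensing genes 10 were lower and 1 higher (the same numbers adjusted over the list alone), with the prolactin receptor Prlr at 49.9 ± 0.60 RPKM against 806 ± 104 and the progesterone receptor Pgr at 4.88 ± 1.4 RPKM against 57.0 ± 0.026. The basal libraries also held luminal genes, picked here after their values were seen. Krt19 was at 386 and 121 RPKM there and at 3126 and 2642 RPKM in mature luminal cells. Fgg was at 208 and 123 RPKM, against 1291 and 1346 RPKM. The luminal progenitor gene Csn3 was at 29.1 and 29.0 RPKM, against 2966 and 3388 RPKM in luminal progenitors. Whether basal cells themselves gave the hormone-sensing RNA was not tested. Antigen presentation and interferon genes were lower for 10 of 20 and higher for 0 (10 and 0 adjusted over the list alone), with H2-K1 at 52.3 ± 3.3 RPKM against 709.8 ± 71. The largest falls were in AW112010 (-8.05), the protease inhibitor Slpi (-6.73) and the defensin Defb1 (-6.68). AW112010 was higher still in mature luminal cells, at 2477 and 3200 RPKM against 379 and 194 RPKM in basal cells. Whether basal cells themselves gave its RNA was not tested either. Luminal progenitor genes were higher for 10 of 15 and lower for 3 (10 and 3 adjusted over the list alone), including the retinaldehyde dehydrogenase Aldh1a3 at 120.5 ± 2.8 RPKM against 4.99 ± 2.3. That list missed the camera threshold (adjusted p = 0.116). Neural crest genes were higher for 6 of 12 and lower for 4 (6 and 4 adjusted over the list alone), with Sox6 higher (2.74) and Ngfr lower (-2.21). Their camera adjusted p was 0.813.

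Camera adjusted p-values were 4.9e-04 for fetal growth, 0.0414 for cartilage-type matrix, 0.0414 for basal and myoepithelial, 3.6e-04 for hormone-sensing and 2.6e-04 for antigen presentation genes. With an estimated correlation these calls were lost, with adjusted p = 0.346, 0.346, 0.616, 0.616 and 0.48 in the same order. Markers of other cell types were also present in the fMaSC libraries. The fat cell gene Car3 was at 82.6 ± 5.4 RPKM against 0.0956 ± 0.14, and Retn at 15.7 ± 2.1 RPKM while listed at 0 in both basal libraries. Of 6 measured markers of this kind 5 were higher (5 adjusted over the list alone; camera, adjusted p = 0.00978, and adjusted p = 0.346 with an estimated correlation). Both measured red cell genes were higher, with Hba-a2, an alpha globin gene that has a near-identical copy, at 179.8 ± 7.8 RPKM and listed at 0 in both basal libraries. Fibroblast genes were higher for 5 of 10 and lower for 1 (5 and 1 adjusted over the list alone). The pigment cell genes Dct and Pmel reached 20.4 ± 3.5 and 16.9 ± 1.0 RPKM in fMaSC and were listed at 0 in both basal libraries.

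In all, 4628 genes were higher and 2941 lower in fMaSC than in basal cells among 12553 tested (limma). The median gene lay 0.27 higher on the log2 scale; after quantile normalization that median was -0.02 and the split 3718 higher and 3809 lower. Without fMaSC replicate 1 the total fell to 4801, and without replicate 2 to 4875.

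Against luminal progenitors, the adult population thought to give rise to secretory cells, fMaSC held more of the basal and matrix genes. Snai2, a transcription factor of basal mammary cells, was at 76.9 ± 4.2 RPKM against 0.0944 ± 0.13 (n = 2 each), and smooth muscle actin Acta2 at 615 ± 9.2 RPKM against 9.44 ± 2.7. Of 16 basal and myoepithelial genes 14 were higher and 0 lower (15 and 0 adjusted over the list alone). Mesenchymal transition genes were higher for 8 of 11 and lower for 1 (8 and 1 adjusted over the list alone), with vimentin (Vim) at 356 ± 5.7 RPKM against 8.09 ± 3.4. Basement membrane genes were higher for 10 of 14 (10 adjusted over the list alone), with the collagen IV chain Col4a1 at 59.8 ± 0.052 RPKM against 1.21 ± 0.47. All 22 cell cycle genes were again higher (22 adjusted over the list alone; camera, adjusted p = 1.5e-11, and adjusted p = 0.0304 with an estimated correlation). Fetal growth and imprinted genes were higher for 11 of 13 (11 adjusted over the list alone), with the cell cycle inhibitor Cdkn1c at 226 ± 29 RPKM against 0.731 ± 0.18. The insulin-like growth factor binding protein Igfbp2 had the largest rise at 293 ± 4.6 RPKM against 0.168 ± 0.030.

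Luminal genes were lower. Of 15 luminal progenitor genes 11 were lower and 2 higher (11 and 2 adjusted over the list alone), with the lipopolysaccharide co-receptor Cd14 at 2.86 ± 0.65 RPKM against 303 ± 6.3 and lactoferrin (Ltf) at 0.302 ± 0.18 RPKM against 45.1 ± 2.7. Keratins of luminal cells led the luminal identity list, of which 9 of 16 genes were lower and 3 higher (9 and 3 adjusted over the list alone). Krt7 was at 2.24 ± 0.94 RPKM against 711 ± 372 and Krt19 at 16.6 ± 0.46 RPKM against 1082 ± 311. Milk protein genes went both ways, with the casein Csn3 lower (-1.90) and Csn1s1 higher (2.70). Of 14 immediate early and heat shock genes 7 were lower (7 adjusted over the list alone), among them Fos (-2.65) and Fosb (-3.43). Of 20 antigen presentation genes 13 were lower (14 adjusted over the list alone), among them H2-K1 (-3.74). The genes with the largest falls were the mucus protein Fcgbp (-8.45) and the lectin Lgals3 (-8.05).

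Camera called 14 of 22 lists with the preset correlation and only the cell cycle list with an estimated one. Of the lists above, the preset adjusted p-values were 1.7e-05 for basal, 0.0384 for mesenchymal, 0.00615 for basement membrane, 1.7e-05 for fetal growth, 3.3e-06 for luminal progenitor and 5.1e-05 for luminal identity genes. They became adjusted p = 0.301, 0.233, 0.301, 0.167, 0.167 and 0.208 with an estimated correlation. For milk protein, immediate early and antigen presentation genes they were 0.0227, 2.7e-04 and 4.2e-08, and adjusted p = 0.194, 0.409 and 0.167 with an estimated correlation. Fat cell markers were higher for 5 of 6 (6 adjusted over the list alone), fibroblast markers for 7 of 10 (7 adjusted over the list alone) and red cell markers for 2 of 2. Of the 12553 genes 4461 were higher and 1888 lower, with a median shift of 0.39 that was -0.04 after quantile normalization and 0.14 with median-of-ratios factors. The split became 3089 and 3142 under the first and 3512 and 2462 under the second. Without fMaSC replicate 1 the total was 3462 and without replicate 2 it was 3516.

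Against mature luminal cells, the hormone-sensing adult population, fMaSC were again high in basal and cell cycle genes and low in hormone-sensing genes. Prlr was at 49.9 ± 0.60 RPKM against 4152 ± 196 and Cited1, a transcriptional co-activator, at 5.17 ± 0.35 RPKM against 505 ± 159.9 (n = 2 each). Of 13 hormone-sensing genes 11 were lower and 1 higher (11 and 1 adjusted over the list alone; camera, adjusted p = 4.1e-10, and adjusted p = 0.201 with an estimated correlation). All 22 cell cycle genes were higher (22 adjusted over the list alone; camera, adjusted p = 2.8e-10, and adjusted p = 0.0383 with an estimated correlation). So were all 13 fetal growth genes (13 adjusted over the list alone; 1.4e-05, and adjusted p = 0.156 with an estimated correlation), with Peg3 at 31.9 ± 0.12 RPKM against 0.394 ± 0.38. The Wnt target and receptor gene Lgr5 was at 70.3 ± 4.2 RPKM against 0.263 ± 0.37. Of 8 Wnt target genes 6 were higher (6 adjusted over the list alone; camera, adjusted p = 0.0282, and adjusted p = 0.201 with an estimated correlation). Notch pathway genes were higher for 7 of 9 (7 adjusted over the list alone), with the ligand Dll1 at 19.3 ± 0.77 RPKM against 0.207 ± 0.023 and the target Hey1 at 41.2 ± 1.7 RPKM against 0.668 ± 0.21. Camera did not call that list (adjusted p = 0.07). The glycolytic enzyme Eno1 was higher (4.87) and the hexokinase Hk2 lower (-3.13) in a hypoxia and glycolysis list with 11 of 15 higher and 3 lower (11 and 3 adjusted over the list alone; camera, adjusted p = 0.28).

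Basal and myoepithelial genes were higher for 14 of 16 (14 adjusted over the list alone; camera, adjusted p = 1.1e-04, and adjusted p = 0.321 with an estimated correlation). Antigen presentation genes were lower for 14 of 20 (15 adjusted over the list alone; 2.8e-10, and adjusted p = 0.156 with an estimated correlation), with the immunoproteasome subunit Psmb8 at 4.63 ± 0.67 RPKM against 139.7 ± 32. The fibrinogen chain Fgb was listed at 0 in both fMaSC libraries and at 1040.0 ± 181 RPKM in mature luminal cells. Schwann and melanocyte markers were higher for 5 of 6 and lower for 1 (5 and 1 adjusted over the list alone; camera, adjusted p = 0.191). Cnp, a myelin enzyme, was at 44.9 ± 2.7 RPKM against 1.60 ± 0.13 and myelin basic protein (Mbp) at 3.56 ± 0.31 RPKM against 34.9 ± 0.79. All 6 measured fat cell markers were higher (6 adjusted over the list alone; camera, adjusted p = 0.00447, and adjusted p = 0.156 with an estimated correlation). So were 2 of 6 endothelial markers (2 adjusted over the list alone; 0.752), among them Cldn5 at 6.14 ± 2.2 RPKM against 1.36 ± 1.6. Of the 12553 genes 5231 were higher and 1849 lower, with a median shift of 0.53 that was 0.00 after quantile normalization and 0.18 with median-of-ratios factors. The split became 3346 and 3246 under the first and 3844 and 2624 under the second. Without fMaSC replicate 1 the total was 4414, and without replicate 2 it was 4404.

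**Figure D2:**
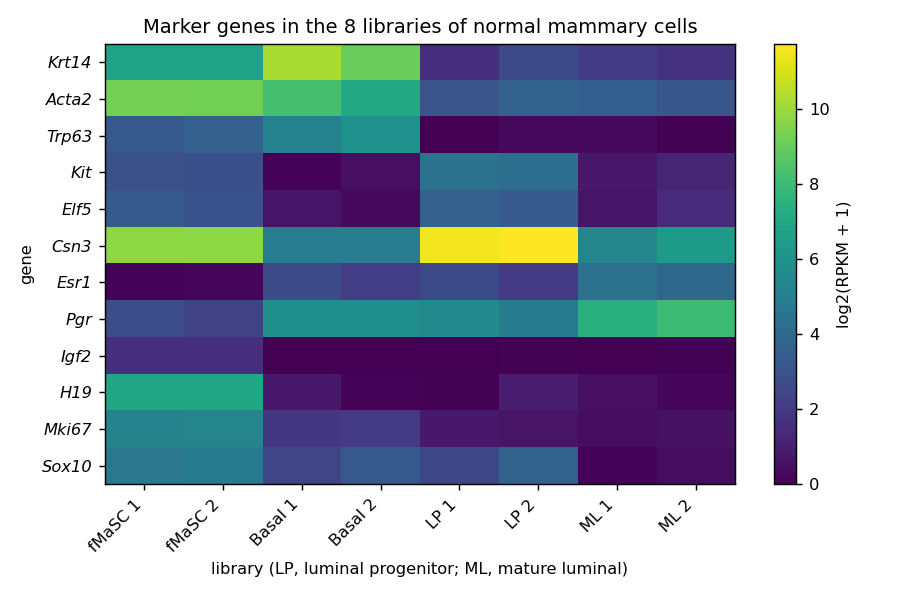
Level of 12 marker genes, as log2(RPKM + 1) by colour, in the 8 libraries of normal mammary cells. H19 and Mki67 are high in both fMaSC libraries, Csn3 peaks in the luminal progenitor libraries, and Pgr is highest in the mature luminal libraries.

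Among the adult cells, basal cells and luminal progenitors parted along the known lineage genes. Krt14, a keratin of basal cells, was at 872 ± 482 RPKM against 3.47 ± 2.1 in luminal progenitors (n = 2 each), and the matrix protein periostin (Postn) at 528 ± 88 RPKM against 3.16 ± 3.5. Of 16 basal and myoepithelial genes 15 were higher and 0 lower in basal cells (15 and 0 adjusted over the list alone). Of 14 basement membrane genes 12 were higher (13 adjusted over the list alone), with Lama3 at 53.1 ± 18 RPKM against 1.16 ± 0.051. All 15 luminal progenitor genes were lower (15 adjusted over the list alone), with Aldh1a3 at 4.99 ± 2.3 RPKM against 815 ± 146 and Csn3 at 29.1 ± 0.090 RPKM against 3177 ± 299. All 7 milk protein genes were lower (7 adjusted over the list alone), a list that shares Csn3 and Lalba with the former. Of the Wnt target list 7 of 8 genes were higher and 1 lower (7 and 1 adjusted over the list alone), with Lgr5 at 119.8 ± 35 RPKM against 1.09 ± 0.042 and Axin2 at 6.43 ± 2.5 RPKM and listed at 0 in both luminal progenitor libraries. The Notch ligands Jag1 (5.74) and Dll1 (4.79) were higher in a Notch list of 9 genes with 4 higher and 2 lower (4 and 2 adjusted over the list alone; camera, adjusted p = 0.248).

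Luminal identity genes were lower for 11 of 16 (12 adjusted over the list alone), among them the tight junction gene Cldn3 (-3.80) and Krt18 (-3.76). Mesenchymal transition genes were higher for 7 of 11 and lower for 1 (7 and 1 adjusted over the list alone), with Snai2 at 49.4 ± 18 RPKM against 0.0944 ± 0.13. Of 6 immune markers 1 was higher, Cd52 at 5.68 ± 1.2 RPKM against 0.887 ± 0.26 (1 adjusted over the list alone; camera, adjusted p = 0.264). Fibroblast markers were higher for 3 of 10 and lower for 1 (3 and 1 adjusted over the list alone; camera, adjusted p = 0.57). Among them were Dcn at 49.8 ± 0.22 RPKM against 9.90 ± 1.7, Fbn1 at 5.02 ± 0.55 RPKM against 0.0647 ± 0.067 and Pdgfrb (0.83), with Lum the lower one (-1.90). Basal replicate 1 held Lyz2, a macrophage gene, at 57.0 RPKM against at most 4.89 in the other 7 normal libraries. With the preset correlation camera called the basal (adjusted p = 2.7e-11), basement membrane (6.1e-08), luminal progenitor (2.7e-12), milk protein (5.0e-06), Wnt target (0.00216), luminal identity (1.2e-05), mesenchymal (0.00111) and cartilage-type matrix (0.0244) lists. With an estimated correlation none held, with adjusted p = 0.176, 0.166, 0.136, 0.136, 0.158, 0.176, 0.158 and 0.176 in the same order. Of the 12553 genes 2641 were higher and 1814 lower in basal cells (limma), and 2242 and 2339 after quantile normalization. A fit on the 2 groups alone gave 2252 in total. Leaving out luminal progenitor replicate 1 or 2 gave 2623 (1787 higher and 836 lower) or 2486 (1504 and 982). Leaving out basal replicate 1 gave 5994, with a near even split of 3142 and 2852, and leaving out basal replicate 2 gave 4814 (2858 and 1956).

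Mature luminal cells differed from luminal progenitors by hormone receptor genes in one direction and secretory genes in the other. Prlr was at 4152 ± 196 RPKM against 574 ± 128 (n = 2 each), and Ly6a, a surface antigen of hormone-sensing cells, at 3617 ± 297 RPKM against 409.6 ± 24. Of 13 hormone-sensing genes 11 were higher and 1 lower (12 and 1 adjusted over the list alone). All 15 luminal progenitor genes were lower (15 adjusted over the list alone), among them the antibacterial protein lipocalin 2 (Lcn2) at 243 ± 79 RPKM against 17243 ± 7716. The iron carrier transferrin (Trf, -6.71) and all 7 milk protein genes were lower too (7 adjusted over the list alone). Of 14 immediate early and heat shock genes 10 were lower (13 adjusted over the list alone), with Egr1 at 40.3 ± 7.4 RPKM against 365 ± 185 and Dusp1 at 46.7 ± 7.2 RPKM against 336 ± 139. Antigen presentation genes were higher for 3 of 20 (2 adjusted over the list alone), among them H2-K1 (0.99). The tight junction gene Cldn1 (-6.66) and complement C3 (-5.08) were among the largest falls, and Wfdc2 (3.89) among the largest rises. The largest rise, in Rpl37rt (7.80), belongs to a retro-copy of Rpl37 and is uncertain because reads may be shared with the parent gene.

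Of markers of other cells, Csf1r, a macrophage receptor gene, was the 1 of 6 immune markers that was higher, at 4.06 ± 0.14 RPKM against 0.651 ± 0.026 (1 adjusted over the list alone; camera, adjusted p = 0.539). The red cell gene Hba-a2 was higher too, at 5.71 ± 4.3 RPKM against 0.894 ± 0.57.

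Camera called the hormone-sensing (adjusted p = 6.3e-08), luminal progenitor (1.4e-13), milk protein (8.0e-07), immediate early (1.8e-06), antigen presentation (0.0267) and cartilage-type matrix (0.048) lists with the preset correlation. With an estimated correlation the values were adjusted p = 0.448, 0.115, 0.115, 0.526, 0.619 and 0.448. Ribosomal protein genes were called higher as a list (adjusted p = 0.0267, and adjusted p = 0.74 with an estimated correlation) with a median of 0.31, although 0 of 24 passed alone (0 adjusted over the list alone). Of the 12553 genes 1083 were higher and 1687 lower in mature luminal cells (limma), a split that became 1458 and 1490 after quantile normalization and 1438 and 1504 with median-of-ratios factors. Each of the 4 libraries mattered to the total, which was 1180 or 932 without mature luminal replicate 1 or 2 and 1170 or 1430 without luminal progenitor replicate 1 or 2.

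In PY230 tumours the luminal SOX10 high and low fractions were compared to ask what accompanies SOX10 within 1 lineage. The SOX10 high cells held more of the genes of milk secretion. Alpha-lactalbumin (Lalba) was at 75.9 ± 59 RPKM against 2.97 ± 1.8 in SOX10 low cells (n = 2 each), Csn3 at 1005 ± 619.6 RPKM against 72.2 ± 17, and transferrin (Trf) at 1069 ± 579.5 RPKM against 62.0 ± 6.5. Of 15 luminal progenitor genes 11 were higher and 0 lower (11 and 1 adjusted over the list alone), with Lcn2 at 3881 ± 1942 RPKM against 276 ± 39.9. All 5 measured milk protein genes were higher (5 adjusted over the list alone). Cartilage-type matrix genes, several of them targets of the related SOX9, were higher for 4 of 7 (5 adjusted over the list alone). Col9a1 was at 43.9 ± 21 RPKM against 2.55 ± 0.14 and Col11a1 at 36.0 ± 7.1 RPKM against 3.08 ± 0.052. Of 16 neural crest genes 7 were higher and 2 lower (7 and 3 adjusted over the list alone), among them Pax3 (5.10 ± 0.99 RPKM against 0.168 ± 0.014) and Sox8 (3.86 ± 0.72 RPKM against 0.334 ± 0.00071) beside Sox10 itself.

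Hormone-sensing genes were lower, 7 of 13 against 1 higher (11 and 1 adjusted over the list alone). Foxa1, a pioneer transcription factor for hormone receptors, was at 43.8 ± 23 RPKM against 141 ± 12 and Cited1 at 308 ± 92 RPKM against 1070.0 ± 256. Luminal identity genes were lower for 7 of 16 and higher for 1 (9 and 1 adjusted over the list alone), with Krt7 at 305 ± 149 RPKM against 927 ± 35. Basal genes at low levels were higher for 8 of 16 (9 adjusted over the list alone), with Krt5 at 14.0 ± 4.5 RPKM against 5.22 ± 2.5. In the basal SOX10 high fraction Krt5 was at 388 and 391 RPKM and Acta2 at 1904 and 1670 RPKM. Acta2 was at 46.5 and 56.7 RPKM in luminal SOX10 high and 35.1 and 18.7 RPKM in luminal SOX10 low cells. Whether luminal cells themselves gave this basal RNA was not tested. Mesenchymal transition genes were higher for 3 of 12 (3 adjusted over the list alone), with the transcription factors Foxc1 (12.2 ± 3.3 RPKM against 1.14 ± 0.21) and Twist1 (8.62 ± 3.6 RPKM against 0.835 ± 0.093). The Notch target Hey1 (2.60), the receptor Notch1 (1.48) and the Wnt factor Tcf7 (0.86) were higher. In the Notch list 4 of 9 were higher and 1 lower (4 and 1 adjusted over the list alone), and in the Wnt list 3 of 6 were higher (4 adjusted over the list alone). The carbonic anhydrase Car9, a hypoxia marker, was at 63.0 ± 14 RPKM against 8.05 ± 2.3. The hypoxia list went both ways (2 higher, 2 lower of 15; 2 and 3 adjusted over the list alone). Immune markers were higher for 4 of 9 (5 adjusted over the list alone), with Tyrobp at 12.0 ± 1.00 RPKM against 4.49 ± 1.1. The class II genes Cd74 (90.8 ± 0.21 RPKM against 33.2 ± 10.2) and H2-Aa (42.8 ± 4.5 RPKM against 16.6 ± 7.8), also genes of immune cells, were higher too. Their antigen presentation list had 6 of 20 higher and 3 lower (7 and 3 adjusted over the list alone; camera, adjusted p = 0.637). Of 3 skin keratinocyte markers 0 passed (0 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.86), with Sbsn at 14.9 ± 1.2 RPKM against 14.2 ± 2.9.

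With the preset correlation camera called the luminal progenitor (adjusted p = 3.6e-06), milk protein (1.2e-04), cartilage-type matrix (0.00345), neural crest (0.0328), hormone-sensing (3.6e-04), luminal identity (0.00255), basal (7.3e-04), mesenchymal (0.00345), Wnt target (0.0328) and immune marker (0.00328) lists. With an estimated correlation the values were adjusted p = 0.385 for all of these except hormone-sensing (0.476), basal (0.485) and immune (0.589) genes. Without Sox10, on which the fractions differ by the sort, camera did not call the neural crest list (adjusted p = 0.085, and adjusted p = 0.385 with an estimated correlation). Fry did call it (adjusted p = 0.012), with 6 of the 15 remaining members higher and 2 lower. Of 13136 genes 1654 were higher and 1320 lower (limma), of which 209 and 1 changed by at least 2 on the log2 scale. The total was 1826 without the filter on low values, 1125 higher and 701 lower. It was 871 without SOX10 high replicate 1 (629 and 242), 778 without SOX10 low replicate 1 (620 and 158) and 470 without SOX10 low replicate 2 (456 and 14). Without SOX10 high replicate 2 it was 3785 (2128 and 1657).

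The basal and luminal SOX10 high fractions of PY230 tumours, which did not differ in Sox10 beyond the spread (log2 fold change -0.13, SE 0.21, adjusted p = 0.649), were compared to ask how lineage varies at a like SOX10 level. Smooth muscle actin (Acta2) was at 1787 ± 165 RPKM against 51.6 ± 7.2 in luminal cells (n = 2 each), Krt5 at 389.7 ± 2.1 RPKM against 14.0 ± 4.5 and Myh11 at 105 ± 37 RPKM against 2.59 ± 0.049. All 16 basal and myoepithelial genes were higher in the basal fraction (16 adjusted over the list alone). All 16 luminal identity genes were lower (16 adjusted over the list alone), with Cldn4 at 24.8 ± 9.2 RPKM against 398 ± 7.5. Basement membrane genes were higher for 12 of 14 and lower for 1 (13 and 1 adjusted over the list alone), with Col17a1, a hemidesmosome collagen, at 354 ± 39.5 RPKM against 9.65 ± 1.8 and Col4a1 at 666 ± 15 RPKM against 31.0 ± 8.2. Snai2 (4.09) and N-cadherin (Cdh2, 3.22) were among 7 of 12 mesenchymal transition genes that were higher, against 1 lower (7 and 1 adjusted over the list alone). The Notch ligands Jag2 (4.49) and Dll1 (4.17) were higher and the receptor Notch3 (-2.31) lower.

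Luminal progenitor genes were lower for 12 of 15 and higher for 2 (12 and 2 adjusted over the list alone), with the receptor kinase Kit at 4.27 ± 0.19 RPKM against 51.5 ± 17. Hormone-sensing genes were lower for 12 of 13 (12 adjusted over the list alone), with Cited1 at 33.8 ± 11 RPKM against 308 ± 92. Cell cycle genes were lower for 18 of 22 (19 adjusted over the list alone), with a list median of -0.72 and the replication helicase subunit Mcm6 at 26.2 ± 3.2 RPKM against 70.1 ± 4.2. Neural crest genes went both ways, 6 higher and 4 lower of 16 (6 and 4 adjusted over the list alone; camera, adjusted p = 0.316), with Erbb3 lower (-3.14) and Mia higher (1.62). Fibroblast markers were higher for 2 of 12 (2 adjusted over the list alone), Dcn at 34.6 ± 2.0 RPKM against 8.69 ± 3.8 and Fbn1 at 21.2 ± 2.3 RPKM against 5.13 ± 2.6. The fat cell marker Fabp4, which endothelial cells also express, was at 67.1 ± 13 RPKM against 8.46 ± 2.2.

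Camera called 11 of 22 lists with the preset correlation. Among them the adjusted p-values were 2.0e-18 for basal, 8.8e-08 for luminal identity, 3.9e-10 for basement membrane, 6.7e-05 for mesenchymal, 0.00799 for luminal progenitor, 0.00112 for hormone-sensing, 0.00104 for cell cycle and 0.00258 for fibroblast genes. The first 4 were, with an estimated correlation, at adjusted p = 0.365 and the rest at adjusted p = 0.458. Of 13136 genes 1814 were higher and 3699 lower in the basal fraction (limma), with a median shift of -0.21 that was -0.06 after quantile normalization and 0.00 with median-of-ratios factors. The split became 2383 and 2780 under the first and 2497 and 2294 under the second. The total was 2996 or 3276 without basal replicate 1 or 2.

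The C3-1-TAg fractions are both titled basal, but markers of both lineages were present, as genes picked after their values were seen show. The basal keratin Krt14 was between 89.7 and 1007 RPKM in the 9 libraries and the luminal keratin Krt18 between 286 and 1029, while Acta2 was at most 10.5 and Myh11 under 1 RPKM. The table has no group of another lineage to compare with, so the lineage of these cells is left open. Of 11948 genes 5 passed the threshold between SOX10 high and low cells, all higher in SOX10 high and all coding for histone H2B, a core protein of the nucleosome. Hist1h2bb was at 117 ± 54 RPKM against 4.40 ± 6.8 (n = 5 and 4), Hist1h2bm at 104 ± 52 RPKM against 3.75 ± 6.1, Hist1h2bf at 38.2 ± 19.8 RPKM against 1.27 ± 2.2, Hist2h2be at 19.1 ± 10.0 RPKM against 1.36 ± 0.95 and Hist2h2bb at 16.1 ± 9.3 RPKM against 1.28 ± 0.50. The log2 fold changes ran from 2.80 to 5.11 (limma, adjusted p = 0.0175 for each). H2B genes are near-identical copies, so the share of reads given to each is uncertain. The summed level of the 5 was between 206 and 550 RPKM in the SOX10 high libraries and 36.5, 3.04, 5.59 and 3.11 RPKM in SOX10 low replicates 1 to 4. At an unadjusted p under 0.05 there were 365 genes, 197 higher and 168 lower, a count that ran from 209 to 809 over the settings run.

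**Figure D3:**
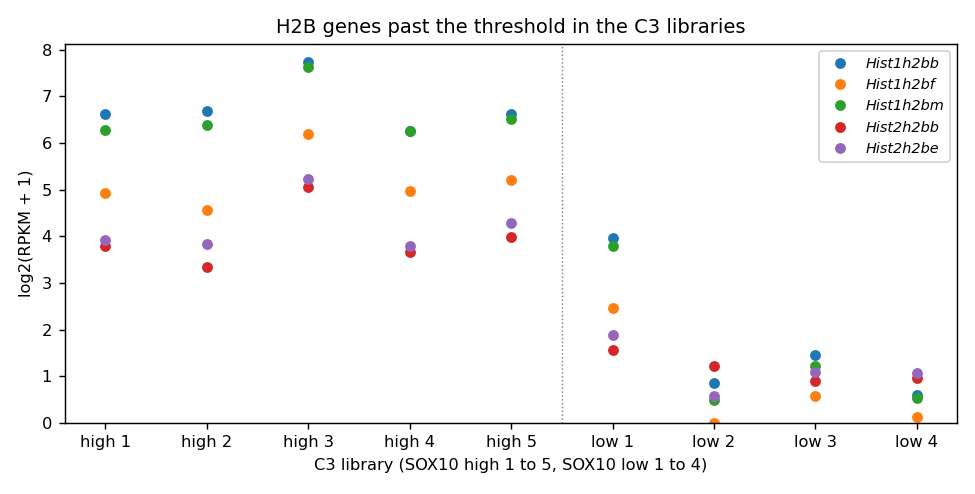
Level of the 5 H2B genes past the threshold, as log2(RPKM + 1), in each of the 9 C3-1-TAg libraries; colours mark genes and the dotted line parts SOX10 high from SOX10 low. The summed level is highest in SOX10 high replicate 3 at 550 RPKM and, among the low libraries, in replicate 1 at 36.5.

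Of the fixed lists, 0 members passed over all genes in C3-1-TAg cells (limma). Camera called 9 of 20 lists with the preset correlation and 0 with an estimated one. Adjusted over the list alone, 3 luminal progenitor, 3 cartilage-type matrix, 1 milk protein and 1 neural crest gene were higher and 1 hypoxia gene lower. The neural crest gene is Sox10 itself, whose difference was fixed by the sort. Fry called 0 of the 20 lists here, against 8 to 18 of 22 in the other comparisons. Luminal progenitor genes had a median log2 fold change of 1.16 (camera, adjusted p = 7.8e-09, and adjusted p = 0.107 with an estimated correlation), with Lcn2 at 1861 ± 1036 RPKM against 793 ± 403. Cartilage-type matrix genes had a median of 1.34 (1.4e-05, and adjusted p = 0.192 with an estimated correlation), with Col9a3 at 62.4 ± 19.7 RPKM against 21.3 ± 9.9. Neural crest genes had 0.14 (0.0255, and adjusted p = 0.32 with an estimated correlation), a call that ended without Sox10 (median 0.09; adjusted p = 0.241, and adjusted p = 0.564 with an estimated correlation). Milk protein genes had a median of 2.49 (0.00854, and adjusted p = 0.461 with an estimated correlation), with Csn3 at 226 ± 412 RPKM against 34.4 ± 65, levels that rest on SOX10 high replicate 1 at 961 RPKM and SOX10 low replicate 2 at 132 RPKM, against at most 102 and 2.23 RPKM in the other libraries of each group. These libraries deviate from their groups together, as do SOX10 high 2 and SOX10 low 3, where Csn3 was at 16.4 and 1.45 RPKM. Within both pairs Csn3 was thus higher in the SOX10 high library, while Lcn2 was higher there in the first pair (2128 and 1289 RPKM) and not in the second (282 and 311 RPKM). A block of these pairs, which were read from the same values, gave 809 genes at an unadjusted p under 0.05 and 3 past the threshold. Hormone-sensing genes had a median of -0.92 (0.00484, and adjusted p = 0.461 with an estimated correlation), with Ly6a at 68.1 ± 79.6 RPKM against 244 ± 174.

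Antigen presentation genes had a median of -0.89 (adjusted p = 1.4e-05, and adjusted p = 0.461 with an estimated correlation), and hypoxia genes one of -0.42 (6.9e-04, and adjusted p = 0.461 with an estimated correlation). Immune markers had a median of -1.28 (camera, adjusted p = 0.00484, and adjusted p = 0.564 with an estimated correlation). Ribosomal protein genes had a median of -0.21 (0.0279, and adjusted p = 0.634 with an estimated correlation). SOX10 low replicate 1 held immune cell RNA, with the leukocyte gene Ptprc at 19.6 RPKM against at most 0.868 in the other 8 libraries, and Lyz2 at 631 RPKM. Leaving that library out kept all 5 H2B genes. The count was 0 without SOX10 high replicate 1, 4 or 5 or SOX10 low replicate 2, 3 or 4. It was 2 without SOX10 high replicate 3 and 11 without SOX10 high replicate 2. The H2B log2 fold changes stayed between 2.53 and 5.87 under these removals, with SE from 0.23 to 0.71 (0.33 to 0.62 with all libraries) and adjusted p of at most 0.0945. Where the count was 0, all 5 adjusted p-values were at least 0.0559. It was 2 with a pseudocount of 0.1, where the H2B log2 fold changes were 3.48 to 6.19 (SE 0.38 to 0.93, adjusted p = 0.0356 to 0.0949), and 0 without the filter on low values. With the values as deposited it was 11, among them 3 of the 5 H2B genes, and all 5 had log2 fold changes of 2.06 to 4.28 (adjusted p = 0.0313 to 0.116). Without the filter the fold changes were the same, with adjusted p = 0.151 over 19715 genes.

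Genes specific to each normal population were then followed in the tumour comparisons, to ask which normal cell the fractions resemble. The luminal progenitor set of 209 genes, of which 184 were measured, leaned towards PY230 luminal SOX10 high cells. In it 86 were higher and 12 lower, with a median log2 fold change of 0.64 (camera, adjusted p = 3.6e-09). The mature luminal set leaned the other way, with 2 higher and 154 lower of 292 and a median of -1.02 (4.1e-25). The basal set had 133 higher and 25 lower of 716 with a median of 0.16 (0.00148). With an estimated correlation all 3 stood at adjusted p = 0.228. By fry the luminal progenitor, mature luminal and basal sets passed, with adjusted p = 0.0146, 0.028 and 0.0184. Whether luminal cells themselves gave the RNA of the basal set was not tested. The fMaSC set of 1829 measured genes had 267 higher and 113 lower and a median of 0.08 (adjusted p = 0.0609). It passed the threshold under both other scalings, with adjusted p = 0.00699 after quantile normalization and 0.0141 with median-of-ratios factors. It was at adjusted p = 0.688 with an estimated correlation, and at 0.466 and 0.45 under these scalings.

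The sets were drawn anew under each setting, and their splits moved. Without the filter the basal set had 75 higher and 10 lower of 772 and the mature luminal set 0 and 52 of 274. The luminal progenitor set had 62 and 3 of 185, and the fMaSC set 171 and 45 of 1936. After quantile normalization the fMaSC set had 166 and 72 of 1090.

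Between PY230 basal and luminal SOX10 high cells the basal set had 289 higher and 46 lower (median 0.32, adjusted p = 1.3e-18, and adjusted p = 0.0641 with an estimated correlation). The luminal progenitor set (median -0.98, 8.9e-07) and the mature luminal set (median -1.19, 5.0e-12) were lower, with adjusted p = 0.341 and 0.351 with an estimated correlation. By fry the adjusted p was 0.00194 for the basal, 0.00277 for the luminal progenitor and 0.0112 for the mature luminal set. The fMaSC set was not called (267 higher and 570 lower, median -0.28, adjusted p = 0.682). These sets were drawn anew under each scaling, so their members and the tumour values changed at once. The basal set had 360 higher and 18 lower of 647 (median 0.68) after quantile normalization and 369 and 18 of 705 (median 0.60) with median-of-ratios factors, in place of 289 and 46 of 716. The fMaSC set had 242 and 259 of 1090 (median -0.13) under the first and 295 and 243 of 1289 (median -0.06) under the second, in place of 267 and 570 of 1829. Its share of positive values was 41.0% and 45.6%, in place of 30.5%. Its lean to lower values was thus weaker under both, and members and scaling cannot be told apart as the reason. In C3-1-TAg cells the luminal progenitor set had a median of 0.12 (4.9e-05, and adjusted p = 0.11 with an estimated correlation) and the mature luminal set of -0.26 (1.5e-07, and adjusted p = 0.153 with an estimated correlation). By fry both stood at adjusted p = 0.274. There the basal set had a median of -0.07 (adjusted p = 0.53). The fMaSC set had a median of 0.01 (adjusted p = 0.109), and its adjusted p was 0.0392 without the filter on low values, 0.0401 after quantile normalization and 0.0315 with median-of-ratios factors. Its call was lost with an estimated correlation, at adjusted p = 0.715 without these settings and at 0.569, 0.456 and 0.269 with them (fry, adjusted p = 0.926, 0.887, 0.476 and 0.54).

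**Figure D4:**
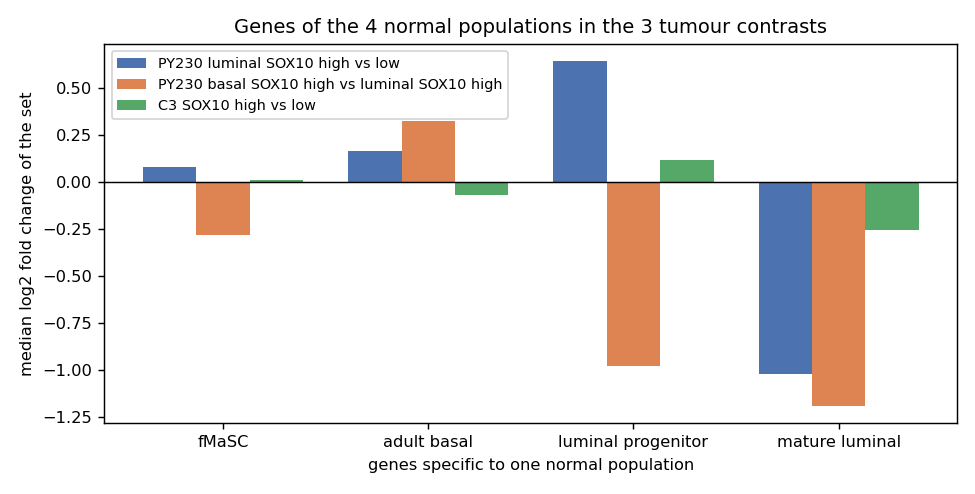
Median log2 fold change of the genes specific to each of 4 normal populations, in the 3 tumour comparisons (bars, coloured by comparison; no error bar is drawn). The mature luminal set lies below 0 in all 3 at -1.02, -1.19 and -0.26, and the luminal progenitor set at 0.64, -0.98 and 0.12.

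The SOX10 comparisons of the PY230 luminal and C3-1-TAg cells share no library. They differ in tumour model, titled lineage and mouse strain at once, so a difference between them cannot be laid to 1 of these. Their log2 fold changes had a Pearson r of 0.274 and a Spearman rho of 0.198 across 11418 genes, which are not independent replicates. Of the 1404 genes higher in PY230 SOX10 high cells 57.3% had a positive value in C3-1-TAg cells (camera, p = 3.2e-06; p = 0.0315 with an estimated correlation; fry, p = 0.179). Of the 1115 lower genes 68.4% had a negative one (p = 1.9e-04; p = 0.181 with an estimated correlation; fry, p = 0.18). The 2 C3-1-TAg calls measured in both tables were not among the PY230 calls, where independent lists would share 0.25 genes (Fisher's exact test, p = 1). In the same exact test 1 of 3 was shared after quantile normalization (p = 0.309) and with median-of-ratios factors 2 of 4 (p = 0.0777), too few calls to tell. A test of the difference itself gave 11 genes (limma), against 931 at an unadjusted p under 0.05. The count of 11 was larger with a pseudocount of 0.1 and without the filter on low values, as given below. Hist2h2be had the larger value in C3-1-TAg cells, with log2 fold changes of 3.06 there and -1.34 in PY230 cells (adjusted p = 0.0182). Foxc1 had the larger in PY230 cells, with 2.61 there and 0.30 in C3-1-TAg cells (adjusted p = 0.0186). The other 9, among them St6galnac6 (2.99 and -0.13) and Btbd19 (2.44 and -0.29), named after their values were seen, also had the larger value in PY230 cells. Sox10 itself did not differ beyond the spread (2.65 and 3.19, adjusted p = 0.958).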

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

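The tests of the H2B genes, the splits that part the pairs of libraries and the block of these pairs were chosen only after the results were seen; the other tests of splits and of the paired libraries were chosen before theirs.

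The 5 H2B genes that separate C3-1-TAg SOX10 high from low cells kept a near-fixed proportion to each other. In the 6 libraries where they summed to at least 10 RPKM, the SD of the log2 ratio between 2 of them had a median of 0.200 over 10 pairs, at most 0.308. A rise shared by the measured histone genes is argued against. The 14 others had a median log2 fold change of 0.170 (-1.65 to 0.80), with 0 past the threshold. Only 2 of the 14 were H2B genes, with a median of 0.379. The cDNA was made from polyA RNA, so histone transcripts without a polyA tail were not covered. Histone transcription in general was therefore not tested. A candidate explanation is 1 transcript with an H2B sequence whose reads were divided among the near-identical genes, for example a fluorescent reporter fused to H2B and driven from the Sox10 gene, though the sources used here name no reporter and none was tested. In PY230 cells Hist1h2bm was at no more than 0.592 RPKM in any library. Hist2h2be went the other way there, at 2.22 and 6.40 RPKM in luminal SOX10 high and 12.8 and 10.0 RPKM in luminal SOX10 low cells. That fall missed the threshold (limma, adjusted p = 0.0522). In basal SOX10 high cells Hist2h2be was at 1.20 and 2.13 RPKM. Whether SOX10 raises an H2B gene of the cell itself stays open.

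Chance cannot be excluded for the count of 5 genes: of 100 drawn splits of the 9 C3-1-TAg libraries, 7 gave at least as many, the real one included. The highest other split gave 332 genes, with SOX10 high 2 and 3 and SOX10 low 1, 3 and 4 set against the rest, which points to a structure of the samples other than SOX10. The splits move all libraries freely, also those that go together in pairs across the fractions (SOX10 high 1 with low 2, and SOX10 high 2 with low 3, r = 0.70). Of the 40 splits that part both pairs as the real one does, only the real one gave as many as 5 genes and the highest other gave 0, but the pairs were read from the same values.

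Part of that structure is a pair of libraries. SOX10 high 1 and SOX10 low 2 deviated from their group means together (r = 0.82 across genes), as did Capza2 and Met, GRCm38 neighbours chosen after their values were seen, at 4729 and 5652 RPKM and at 2126 and 2143 RPKM there, against at most 81.1 and 22.4 RPKM in the other 7 libraries. A difference in scale is argued against, since r was 0.807 after quantile normalization. Extra copies of this chromosome segment in 1 tumour sorted into both fractions may be a cause. The 6 nearest measured genes had a median log2 difference of 0.679, with Met, already seen to be high, among them. Next to Capza2 on either side, Met was higher by 7.21 and St7 by 2.84 (61.6 and 65.5 RPKM against at most 11.8). The genes further out ran from -1.46 for Tspan12 to 0.87 for Lsm8. A median over 6 genes cannot register a segment that holds only the nearest ones. Extra copies and regulation of single genes therefore cannot be told apart. The labels do not say which libraries share a tumour.

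Single values of C3-1-TAg libraries stood apart from the others of their group in 15 of 56 groups of values tested (Dixon's Q on RPKM, not on the log2 scale). Chance gives about 1 in 20 for independent genes with normal values. RPKM need not be normal, and the H2B genes behind 8 of the 15 are not independent, so an excess over chance cannot be judged. Sox10 was lowest in SOX10 high 2 at 91.9 RPKM, against 144 to 164 in the other 4. SOX10 high 3 stood above the rest for Hist1h2bm (196 RPKM), Hist1h2bb (212), Hist1h2bf (72.6), Hist2h2be (36.5) and Hist2h2bb (32.3). Among the SOX10 low libraries replicate 1 was highest for Hist1h2bm (12.8), Hist1h2bb (14.5) and Hist1h2bf (4.498). SOX10 high 1 held H19 at 114 RPKM and Csn3 at 961, and SOX10 low 2 held Csn3 at 132. SOX10 low 1 was highest for Lyz2 (631), Col1a1 (116) and Fabp4 (20.6).

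The difference between the SOX10 high and low fractions was not the same in the PY230 luminal and the C3-1-TAg cells for 2 of 83 named genes tested; SOX10 itself was not perturbed. The titled lineage and the mouse strain differ along with the tumour model here, and the 3 cannot be told apart. The C3-1-TAg minus PY230 difference on the log2 scale was 4.40 for Hist2h2be (adjusted p = 0.0182) and -2.31 for Foxc1 (adjusted p = 0.0186).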

How the results depend on the processing

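Settings chosen only after results were seen were the values as deposited, the joint removal of 2 C3-1-TAg libraries, the crossed pairing, the block of pairs seen in the values, the estimated correlation, and the settings tried on the lists and on the difference between tumour models. No gene called in a comparison was called in the opposite direction under any setting run. Turns of sign that fell short of a call were looked for only among the named genes, where no called gene turned. Apart from the counts named here the number of genes called in a comparison stayed within 1.5 times. Splits between higher and lower genes, and the counts within population sets, moved further and are given with the results. The C3-1-TAg count of 365 at an unadjusted p under 0.05 was 209 with the replicate block, 603 without the filter and 809 with the block of pairs. The C3-1-TAg count of 5 was 2 with a pseudocount of 0.1, 0 without the filter on low values, 11 as deposited, 3 with a block of the pairs seen in the values, and 0 without SOX10 high 1 and SOX10 low 2. Without these 2 libraries the H2B log2 fold changes were still 2.87 to 4.85 (2.80 to 5.11 with all), with SE of 0.39 to 0.72 (0.33 to 0.62 with all) and adjusted p = 0.198. PY230 luminal cells gave 1826 calls without the filter in place of 2974, and basal cells against luminal progenitors 2252 from the 2 groups alone in place of 4455. The lists called by camera fell from 77 to 3 with an estimated correlation. That correlation was estimated from 4, 3 and 7 residual degrees of freedom in the normal, PY230 and C3-1-TAg tables, and its power was not checked. It called 0 lists between PY230 basal and luminal SOX10 high cells, where all basal and myoepithelial genes were higher. Lost calls therefore do not argue against a difference in these lists. Fry called 8 to 18 of 22 lists in each comparison other than C3-1-TAg, where it called 0 of 20. The difference between models gave 27 genes with a pseudocount of 0.1 and 165 without the filter, in place of 11. The fMaSC set passed the threshold in PY230 luminal cells with a median of 0.0543 after quantile normalization and 0.0960 with median-of-ratios factors, and in C3-1-TAg cells with 0.0083 without the filter, and 0.0585 and 0.0429 under the other scalings. The fMaSC set passed in none of these with an estimated correlation. The cause was not tested.

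Leaving out 1 library gave 4801 to 8199 calls for fMaSC against basal cells, 3462 to 4810 against luminal progenitors and 4404 to 5587 against mature luminal cells. It gave 2486 to 5994 for basal cells and 932 to 1430 for mature luminal cells against luminal progenitors. The range was 470 to 3785 for PY230 luminal cells, 2996 to 5509 for PY230 basal cells and 0 to 11 for C3-1-TAg cells. In groups of 2 the lone library is then assumed to vary like the other groups. The Sox10 difference in C3-1-TAg cells ran from 2.41 to 3.67. Of 2353 called values of named genes under these removals 1954 kept their call and 399 lost it. Of 607 called values 591 kept it with median-of-ratios factors, 588 with a pseudocount of 0.1, 576 after quantile normalization and 547 without the filter. For 54 fold changes of 28 named genes some settings gave no value, since the gene fell under the filter.

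Libraries share only a replicate number. Same-numbered libraries had deviations correlated by 0.00 to 0.22 in the normal, -0.26 to 0.30 in the PY230 and -0.34 to 0.20 in the C3-1-TAg table, where 1 of 9 libraries correlated best with its own number. With the replicate block the counts were 7639, 6482, 7188, 4558 and 2793 for the normal comparisons in the order above, 2578 and 5092 for PY230 and 0 for C3-1-TAg replicates 1 to 4, where leaving out SOX10 high 5 alone already gave 0. The H2B log2 fold changes were still 2.80 to 5.13 with that block (SE 0.38 to 0.64, limma, adjusted p = 0.427 to 0.619). Crossing the numbers of the PY230 luminal SOX10 low libraries gave 3806. Absolute depth is unknown, so it cannot be said which low genes it limits.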

Other observations

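The tests of other cell types in the fMaSC libraries were chosen only after the result was seen.

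Beyond the comparisons of groups, single C3-1-TAg libraries stood apart in the genes given here, which were picked after their values were seen. SOX10 low 1 was rich in transcripts of macrophages and antigen-presenting cells, with Cd74, the invariant chain of class II antigen presentation, at 1202 RPKM, H2-Aa at 792 RPKM, the complement gene C1qa at 624 RPKM and the adaptor Tyrobp at 246 RPKM. In SOX10 high 1 and SOX10 low 2, fibronectin (Fn1) was at 6.04 and 9.89 RPKM against 154 to 641 in the other 7, and the cartilage proteoglycan Acan at 0.394 and 0.067 RPKM against 10.0 to 48.1. The collagen IV gene Col4a1 went the other way in that pair, at 209 and 83.3 RPKM against at most 23.2. SOX10 high 2 and SOX10 low 3 formed a second pair with deviations correlated by 0.70 across genes, and held periostin (Postn) at 437 and 1026 RPKM against at most 147 in the other libraries.

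The fMaSC libraries held transcripts of fat, pigment and red cells that were absent or near 0 in most adult libraries. Of 8 fat cell markers, 6 lay higher in both fMaSC libraries than in each adult one (Adipoq, Plin1, Cidec, Retn, Cfd and Car3, with Car3 at 86.4 and 78.9 RPKM), so fat cell RNA among the sorted cells may be present. Fabp4, the most abundant of them, was at 119 and 102 RPKM in fMaSC and at 233 RPKM in basal replicate 2. Endothelial cells also express Fabp4, and basal replicate 2 was higher than basal replicate 1 in some endothelial genes. Emcn was at 25.1 RPKM there against 0.462 RPKM, and Cdh5 at 7.30 against 1.27 RPKM, while Kdr and Egfl7 were lower. Of the pigment cell genes Dct was at 17.9 and 22.9 RPKM, and Pmel (16.2 and 17.7 RPKM), Tyr (1.45 and 2.30) and Slc45a2 (0.677 and 0.444) also lay above each adult library. Tyrp1 and Mlana stayed at no more than 0.0115 of the Dct level. With markers on either side, pigment cells and expression of these genes by fMaSC cannot be told apart, and the sort gates are not given in the sources used here.

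The beta globin genes Hbb-bs and Hbb-b1 stood at 95.3 and 0.882 RPKM in fMaSC replicate 1 and at 0.699 and 94.6 RPKM in replicate 2. The 2 genes are near-identical, so their reads may have been given to one gene in 1 library and to the other gene in the other; this was not tested. Without fMaSC replicate 1 or 2 there were 4801 or 4875 calls against basal cells.

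Some of these patterns can be tested further. Reads that join an H2B sequence to a reporter sequence would tell a fused transcript, as the ratio spread of 0.200 between H2B genes allows, from transcription of H2B genes themselves. DNA copy number next to Capza2, where the median difference of the 6 nearest genes was 0.679, would tell extra copies from regulation. Staining sorted fMaSC for ADIPOQ together with the epithelial marker EPCAM would help to tell fat cells from expression by the fetal cells. ADIPOQ alone could not.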
